A study of Mus musculus with 36 samples.

How the data were processed

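RNA was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read most exons of each gene with many probes, from cells sorted out of fetal mouse gonads. Per the labels' protocols, gonads of time-mated females were collected, pooled by sex, dissociated with trypsin, stained with the dead-cell dye DAPI and sorted by fluorescence, and the RNA was labelled with biotin. The 36 arrays fall into 12 groups of 3, given by the sample titles and characteristics: germ cells and supporting cells, XX and XY, at the stages labelled TS13, TS24 and TS34, which the labels place before, during and after the start of sexual differentiation. Germ cells were marked by an Oct4 reporter in mice of mixed C57BL/6NJ descent at every stage. Supporting cells were marked by a Sry-EGFP reporter on CD-1 in all XX groups and in the XY group at TS13, and by a Tg(Sox9-cre/ERT2) line on C57BL/6 in the XY groups at TS24 and TS34. Cell type and, for supporting cells, part of sex and stage are therefore tied to the mouse line. The interstitial and stromal samples named in the design text were not analysed here.

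The deposited values are log2 expression values per probe set, summarised with RMA (background correction and summarisation over the probes of a set) per the submitters' processing notes. The RMA version, the software and the probe set definition are not given in the sources used here. The table held 35557 probe sets, and all 36 of its columns were mapped to samples. No 2 columns were identical. Array medians ran from 6.412 to 6.841 and single values from 3.179 to 15.085, so the deposited values did not share 1 distribution, and they were used without a further normalization. Whether quantile normalization, usually a part of RMA, was left out or done on a larger set of arrays is not known. For arrays the number of arrays, not a read depth, limits the precision, and low values approach the background of the array, where differences are compressed.

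Probe sets were named through the platform annotation supplied with the series. Of the probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 12147 were not listed there and stayed unnamed. Of the 21789 symbols, 21698 were updated by Entrez identifier to the symbols of the RefSeq annotation of the mouse assembly GRCm38.p6, and 91 kept the platform's symbol. That annotation was used for symbols and chromosome names alone. For each of the 19938 genes the probe set with the highest mean over all arrays was kept (999 genes had more than 1), and probe sets with several symbols were not named. A gene was tested where its value exceeded the 25th percentile of its array on at least 3 arrays, which kept 17615 genes and removed 2323.

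Differences were estimated with limma 3.58.1 in R 4.3.3 as 1 mean per group over all 36 arrays, with moderated variances (24 residual and 11.52 prior degrees of freedom) and no covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested (two-sided). Every adjusted p given for a gene comes from limma. There were 17 comparisons: XY minus XX within each cell type and stage (6), each stage minus the stage before within each cell type and sex (8), the sex difference at TS34 minus that at TS13 in each cell type (2), and germ minus supporting cells averaged over stages and sexes (1). Differences are log2 values with their standard error (SE), each group mean resting on 3 arrays, and the median SE of a difference of 3 against 3 arrays was 0.219. Groups of 3 give few degrees of freedom of their own, so the groups shared 1 estimate of each gene's spread. The labels do not say whether replicates are separate pools of animals, so p-values measure only the spread between these samples, which may be technical.

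The procedure was tested on simulated data drawn with the real genes' means and spreads. For the comparison of XY and XX germ cells at TS34, 9 of 67 genes changed by 0.5, 44 of 67 changed by 1 and 65 of 66 changed by 2 (log2) were called in the right direction, with 11 of the unchanged genes called. For the germ cell sex difference at TS34 minus that at TS13 the numbers were 1 of 67, 15 of 67 and 58 of 66, with 5 unchanged genes called. A comparison with no simulated change called 0 genes. The simulated noise was independent between genes and shifted no array as a whole. The real arrays differ in overall level, so these numbers do not bound the false calls among them.

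The following 21 gene lists were fixed, with the comparisons, the rule for named genes and the other settings listed below, before the data were examined: Sertoli, pregranulosa, WNT targets, gonadal progenitor, germ identity and pluripotency, meiosis, male germ fate and piRNA, Nodal signalling, retinoic acid, basement membrane and cord matrix, cholesterol synthesis, cell cycle, steroidogenic, interstitial and stromal, endothelial, macrophage, erythroid, mesonephric epithelium, dissociation stress, Y-linked, and the X-inactivation centre. For each list the called members were counted over all genes tested and again adjusted over the list alone, and the list was compared with all other genes by limma's camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The X-inactivation centre list, of which Xist was measured, had no set test. Genes of the lists that had no probe set of their own, among them Hbb-bs, Ddx3y, Tsix, Insl3 and Lhcgr, were not analysed here.

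Named genes followed a rule, and the text uses a part of the genes it allows. For each comparison these are the reporter genes Sry, Sox9 and Pou5f1 and the sex check genes Xist, Eif2s3y, Kdm5d and Uty. They include the 6 genes with the largest rise and the 6 with the largest fall among called genes whose groups do not overlap on any array (10 of each for germ minus supporting cells), leaving out predicted genes, small RNAs, olfactory and vomeronasal receptors and ribosomal protein genes. From each list they include up to 5 called members with the largest difference, every called member that goes against the others, and up to 3 members not called. Interactions use genes named under these parts, but the condition that groups do not overlap was not applied to their largest rises and falls.

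The library labelled germ XX TS24 replicate 3 held a somatic profile. Every result was therefore computed again on the other 35 arrays (23 residual degrees of freedom), a choice made after the data were seen, and the named-genes rule was applied again to the 4 comparisons that use this array. In the other comparisons the SE and calls of named genes keep the spread shared by all arrays. That spread is wide for genes on which this library stood apart, such as Pdgfra and Sycp1. Such genes can miss a call there and are then not shown to be unchanged. The other settings, fixed beforehand, were every probe set tested on its own, the mean over the probe sets of a gene, no filter or a filter at the 50th percentile (13040 genes), quantile normalization, median centring of each array, fits on the arrays of 1 cell type or of the groups compared alone, eBayes with trend and robust variances, array quality weights, the replicate number as a block, a minimum change of 2-fold, and each array left out in turn. The X-linked genes, 611 tested against 16927 autosomal genes, were compared by median and by camera. Regroupings of the arrays were refitted, all 10 for comparisons of 3 against 3 and 100 for the others. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sample was left out of the comparisons as designed, and no protein or other layer was measured.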

Results

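Gene expression was measured in 36 samples of sorted fetal gonad cells, 18 of germ cells and 18 of supporting cells, the somatic lineage that gives rise to Sertoli cells in the testis and pregranulosa cells in the ovary. Each cell type was collected from XX and XY gonads at 3 stages, TS13, TS24 and TS34, with 3 arrays in each of the 12 groups. The design follows both cell types across the start of sexual differentiation. Values are log2 expression, and each difference is given ± its standard error on the log2 scale with n = 3 arrays per group unless stated. Arrays of 1 group correlated with each other at r of 0.9631 to 0.9915 over all probe sets, apart from the pairs that held the library labelled germ XX TS24 replicate 3, which went down to 0.9222. Genes were measured by symbol, and 17615 entered the tests.

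The markers of the sort followed the labels on 35 of the 36 arrays. Pou5f1, the gene behind the Oct4 reporter, had group means of 9.98 to 11.46 in the 5 other germ groups and of 5.16 to 5.64 in the 6 supporting groups. The germ cell RNA helicase Ddx4 had means of 10.76 to 11.97 in those germ groups and at most 5.82 in supporting groups, and the somatic gonad factor Wt1 lay at 10.87 to 11.63 in supporting groups. The Y-linked translation factor gene Eif2s3y was at 9.03 to 9.96 in XY groups and at 4.47 to 4.92 in XX groups. The library labelled germ XX TS24 replicate 3 went against its label. It had Pou5f1 at 5.07, where the other 2 arrays of its group averaged 10.70, Ddx4 at 5.04 against 11.31, Wt1 at 11.19 against 7.69 and the stromal receptor Pdgfra at 10.60 against 6.86. Eif2s3y was low on it, at 4.58, and Xist was high, at 11.03. The counts of called genes in comparisons that use this group are given with and without this library. Xist, the RNA that coats the inactive X chromosome, averaged 7.06 ± 0.55 (SD) in XX germ cells at TS13 and 6.91 ± 0.16 at TS34, against 11.25 ± 0.04 and 11.24 ± 0.15 in XX supporting cells. In germ cells the XY minus XX difference of Xist was called at TS24 alone, at -1.69 ± 0.33 without that library. The 2 XX arrays behind it had Xist at 6.60 and 8.29, and the array with 8.29 also had the higher Wt1 (8.19 against 7.18). The stromal gene Dcn was lower in XY in the same comparison, at -1.24 ± 0.31.

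**Figure D1:**
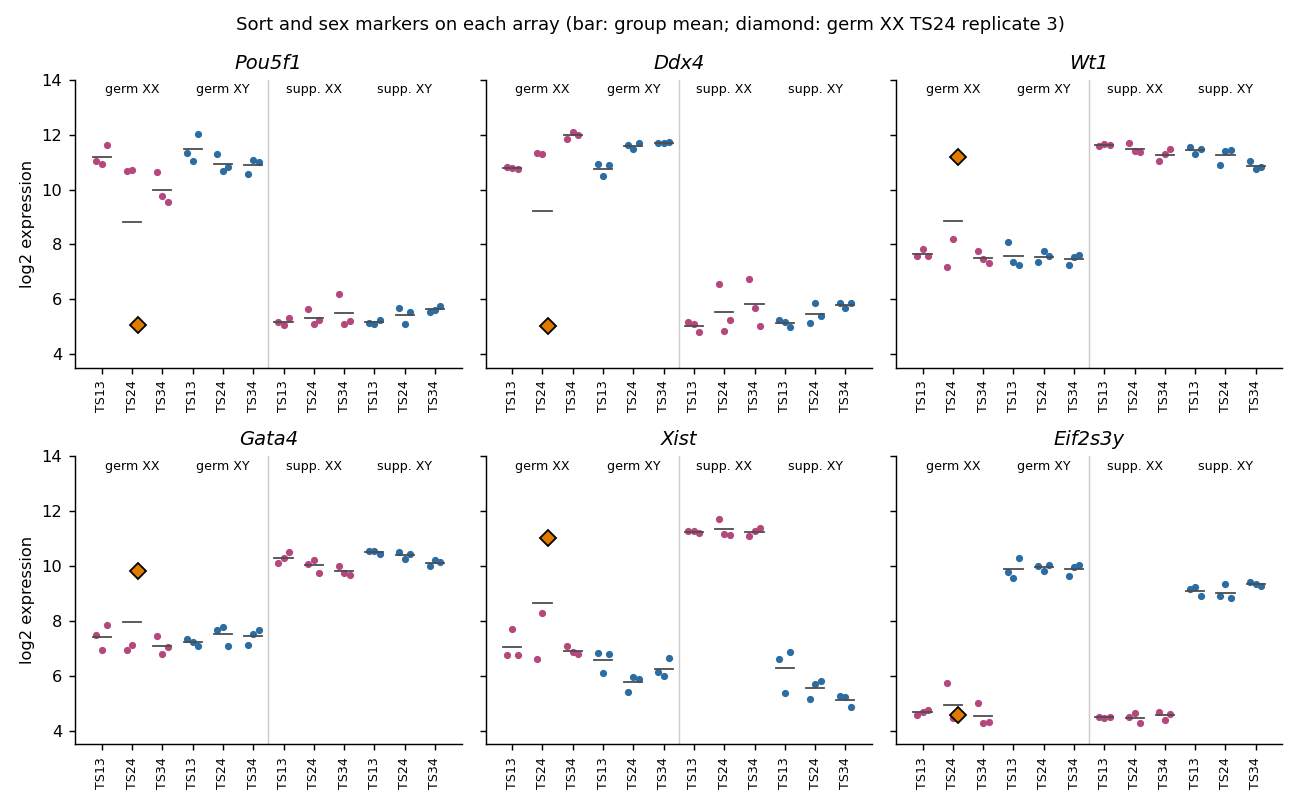
Expression (log2) of 6 marker genes on each of the 36 arrays, by cell type, sex and stage, with each point an array, each bar a group mean and the diamond the library labelled germ XX TS24 replicate 3. Pou5f1 lay at 5.07 on that library, inside the range of the supporting arrays, and Eif2s3y parted XY from XX in every pair of groups.

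Germ and supporting cells differed widely, each expressing the genes of its own lineage. Without the library of somatic profile, the pluripotency-associated gene Dppa5a was higher in germ cells by 6.21 ± 0.15, Ddx4 by 5.89 ± 0.11, the testis cytochrome c gene Cyct by 5.68 ± 0.10 and Pou5f1 by 5.48 ± 0.11 (n = 17 germ and 18 supporting arrays). Kitl, a ligand that germ cells depend on, was lower in germ cells at -4.82 ± 0.10, the reductase gene Akr1cl at -5.25 ± 0.10, Wt1 at -3.75 ± 0.09 and Gata4 at -2.91 ± 0.09. With all arrays, every one of the 20 germ identity and pluripotency genes was higher in germ cells. All 19 cell cycle genes were higher, for example the spindle checkpoint kinase Bub1 by 3.78 ± 0.16 and Mki67 by 2.32 ± 0.11. Of the 15 cholesterol synthesis genes 12 were higher, for example the squalene epoxidase gene Sqle by 1.27 ± 0.09. Of 25 Sertoli genes 24 were lower in germ cells, of 15 gonadal progenitor genes 11 were lower and 3 higher (Six4, Map3k4 and Cbx2). Of 21 basement membrane and cord matrix genes 13 were lower and 2 higher, the fibronectin gene Fn1 by 3.77 ± 0.10 and the nidogen gene Nid2 by 2.77 ± 0.10. The counts adjusted over the list alone were the same for these lists. Camera gave adjusted p = 6.22e-15 for germ identity, 6.22e-15 for cell cycle, 0.00189 for cholesterol synthesis, 1.95e-06 for gonadal progenitor, 0.00189 for matrix and 2.02e-19 for Sertoli genes. With an estimated correlation the Sertoli list alone held (adjusted p = 0.00363), and the others had adjusted p of 0.0542 to 0.205 with an estimated correlation. Without the library of somatic profile the germ identity (0.00354), cell cycle (0.00831) and gonadal progenitor lists (0.0135) also held with an estimated correlation, and cholesterol synthesis (0.212) and matrix (0.316) did not. The counts were then 20, 19 and 13 higher for germ identity, cell cycle and cholesterol synthesis, 24 and 12 lower for Sertoli and gonadal progenitor, and 14 lower and 2 higher for matrix. Immediate early genes that cell handling can induce were lower in germ cells, 10 of the 11 dissociation stress genes being called, for example Jun at -2.88 ± 0.21 and Fosb at -2.32 ± 0.16 (camera adjusted p = 1.67e-06, adjusted p = 0.127 with an estimated correlation, and 0.0237 without the library). In all, 8917 genes were called, 5583 higher and 3334 lower in germ cells, and 9346 (5785 and 3561) without the library of somatic profile. Cell type cannot be told apart from the mouse line, and the direction of the split rested on scaling, with 4189 higher and 5017 lower after quantile normalization and 4714 and 4462 after median centring.

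At TS13 XY and XX germ cells differed at 5 genes, all Y-linked and all higher in XY. These were Eif2s3y (5.21 ± 0.23, adjusted p = 2.48e-18), Uba1y (4.11 ± 0.19), the histone demethylase genes Kdm5d (2.80 ± 0.22) and Uty (2.74 ± 0.24), and Zfy1 (2.68 ± 0.23). No member of the meiosis, male germ fate and piRNA, germ identity and pluripotency or Nodal signalling lists was called by limma, and 366 of all genes had an unadjusted p under 0.05. Of the 6 tested Y-linked genes 4 were higher, also adjusted over the list alone (camera adjusted p = 3.31e-52, and adjusted p = 6.11e-09 with an estimated correlation).

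At TS24 3 of 7 Nodal signalling genes were higher and 4 of 19 meiosis genes lower in XY than in XX germ cells. The values that follow are without the library of somatic profile, which leaves 2 XX against 3 XY arrays. Tdgf1, a Nodal co-receptor, was higher in XY by 2.89 ± 0.29, and its pathway companions Lefty1 and Lefty2, antagonists that Nodal induces, by 1.32 ± 0.26 and 0.97 ± 0.26. These 3 of 7 Nodal signalling genes were called, also adjusted over the list alone (camera adjusted p = 1.21e-04, adjusted p = 0.0731 with an estimated correlation). Nodal itself (0.40 ± 0.23) was not called, nor were Acvr2b (-0.40 ± 0.21) and Acvr1b (-0.16 ± 0.21) of this list. The glutathione transferase gene Mgst2 was higher by 3.55 ± 0.37, the cystatin gene Cst9 by 2.89 ± 0.34 and the ETS factor gene Etv1 by 2.78 ± 0.27. Cst9 is on the Sertoli list, of which Gatm was also called higher (1.77 ± 0.28) and Sox9 was not called (-0.31 ± 0.24). Of 19 meiosis genes 4 were lower in XY (4 lower and 1 higher adjusted over the list alone). They were Stra8, the retinoic acid target needed to enter meiosis, at -1.75 ± 0.24, the meiotic cohesin gene Rec8 at -1.11 ± 0.26, Msh4 at -0.98 ± 0.22 and Meioc at -1.24 ± 0.33 (camera adjusted p = 5.20e-05, adjusted p = 0.250 with an estimated correlation). The Meioc difference rests on 1 of the 2 XX arrays, which had 8.055 and 5.562, where XY arrays had 5.262 to 5.808. The imprinted gene Phlda2 was lower at -3.00 ± 0.25, AU015836 at -3.22 ± 0.31, the WNT-acylating enzyme gene Porcn at -2.18 ± 0.21 and the differentiation inhibitor Id2 at -2.09 ± 0.34. Of the retinoic acid list the synthesising enzyme gene Aldh1a1 was higher (1.56 ± 0.25), while the binding protein genes Crabp1 and Crabp2 were lower (-1.27 ± 0.30 and -1.28 ± 0.30), and Stra8 is a member too (camera adjusted p = 0.393). Limma called 344 genes, 87 higher and 257 lower in XY. With all arrays it called 767 (262 and 505), of which 217 were shared in direction with the 344. There the meiosis list had 1 gene higher (Sycp2) and 1 lower (Rec8), and 6 germ identity genes were higher instead of 1 higher and 1 lower. From the 767, leaving out XX replicate 1 or 2 gave 1912 or 1275 genes, and leaving out XY replicate 1, 2 or 3 gave 430, 179 or 416. The fits without XX replicate 1 or 2 kept the library of somatic profile beside the other XX array. Their counts do not measure the stability of a germ cell difference.

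At TS34 part of the meiosis list parted the sexes. Stra8 was lower in XY than in XX germ cells at -4.65 ± 0.35 (means 5.57 and 10.22, adjusted p = 4.04e-12) and Meioc at -4.55 ± 0.37. Also lower were the single-strand binding protein genes Meiob and Spata22 at -3.99 ± 0.42 and -3.49 ± 0.21, and M1ap at -3.93 ± 0.34. Of 19 meiosis genes 9 were lower and none higher (17 lower adjusted over the list alone), including the hotspot methyltransferase gene Prdm9 (-2.86 ± 0.27) and the recombinase gene Dmc1 (-2.57 ± 0.46). The list had a camera adjusted p = 5.55e-22 and an adjusted p = 0.0178 with an estimated correlation. Nanos2, an RNA-binding regulator of the male germ cell fate, was higher in XY by 3.90 ± 0.23 (means 9.86 and 5.96). Mgst2 was higher by 4.50 ± 0.37, the homeobox gene Hesx1 by 3.52 ± 0.24 and Tdgf1 by 3.37 ± 0.36. Of 19 male germ fate and piRNA genes 5 were higher and none lower, also adjusted over the list alone, with Morc1 at 2.68 ± 0.31, Tdrd5 at 2.42 ± 0.42 and the PIWI gene Piwil4 at 1.57 ± 0.22 (camera adjusted p = 5.10e-04, adjusted p = 0.568 with an estimated correlation). Nodal signalling had 3 of 7 genes higher, Tdgf1, Lefty1 (1.60 ± 0.25) and Lefty2 (1.34 ± 0.24). Adjusted over the list alone 4 were higher, with adjusted p = 5.30e-06 and an adjusted p = 0.0144 with an estimated correlation. Germ identity and pluripotency had 5 of 20 genes higher (7 higher and 1 lower adjusted over the list alone), among them Nanos3 at 1.84 ± 0.28 and Zfp42 at 1.47 ± 0.40 (camera adjusted p = 0.00181, adjusted p = 0.793 with an estimated correlation). Of 12 WNT targets 3 were lower, Ccnd1 at -1.41 ± 0.28, Axin2 at -0.70 ± 0.20 and Notum at -0.64 ± 0.20 (4 adjusted over the list alone, camera adjusted p = 0.00757, adjusted p = 0.341 with an estimated correlation). The G1 cyclin genes Ccne2 and Ccne1 were the called cell cycle genes, both lower (-1.55 ± 0.30 and -1.30 ± 0.31). Among Sertoli genes Cst9, Defb19 (1.81 ± 0.32) and Hsd17b3 (1.28 ± 0.21) were higher in XY germ cells (camera adjusted p = 0.0268, adjusted p = 0.660 with an estimated correlation). Limma called 1291 genes, 727 higher and 564 lower, and 1844 with the residual spread estimated without the library of somatic profile, the 1291 among them. Without XX replicate 3 or XY replicate 3 the count was 705 or 814. Setting XY replicate 1 with XX replicates 2 and 3 against the other arrays, a split by overall level, called 3910 genes, so a structure beside sex parts these arrays.

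**Figure D2:**
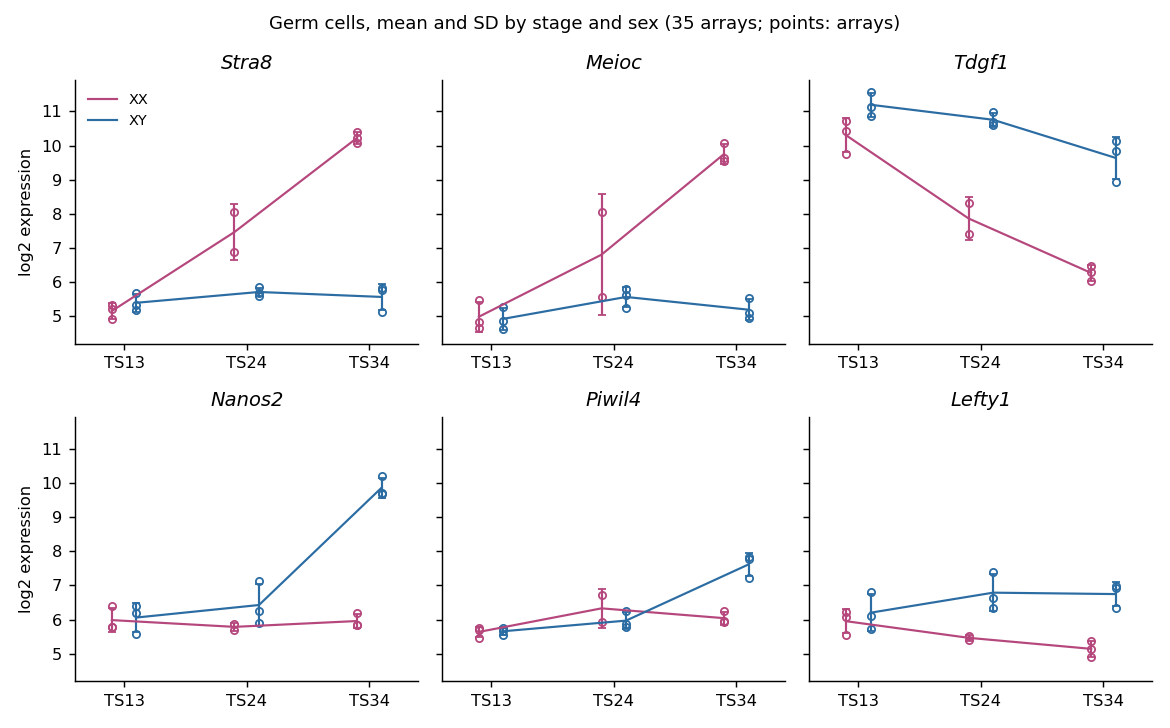
Expression (log2) of 6 genes in germ cells by stage and sex on 35 arrays, with points for arrays, lines through group means and error bars of 1 SD. Stra8 reached a mean of 10.22 in XX against 5.57 in XY at TS34, and Nanos2 a mean of 9.86 in XY against 5.96 in XX.

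X-linked genes as a group lay lower in XY than in XX germ cells. The median difference of X-linked genes minus that of autosomal genes was -0.045 at TS13, -0.192 at TS24 and -0.154 at TS34 (camera, n = 611 genes, p = 0.00522, 2.07e-06 and 5.67e-07). With an estimated correlation the p was 0.435, 0.190 and 0.168. After quantile normalization it was 4.68e-04, 1.23e-07 and 9.20e-08 with medians of -0.043, -0.200 and -0.152, and both settings were added after the data were seen. The size of the gap depended on the filter on dim genes, with -0.099, -0.300 and -0.277 for a filter at the 50th percentile and -0.019, -0.141 and -0.116 for none. At TS24 58 X-linked genes were called higher in XX and 7 in XY (44 and 1 without the library of somatic profile), and at TS34 87 and 19 (112 and 33 with the spread estimated without it). In supporting cells the medians were -0.010, -0.023 and -0.023 (n = 611 genes, p = 0.539, 0.443 and 0.842).

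In XX germ cells meiotic genes rose over both steps. The values without the library of somatic profile were a rise of Stra8 by 2.31 ± 0.24 from TS13 to TS24 and by a further 2.75 ± 0.24 to TS34, and for Meioc 1.82 ± 0.33 and 2.94 ± 0.33 (n = 3, 2 and 3 arrays at the 3 stages). The first rise of Meioc rests on replicate 1 at TS24 (8.055, against 5.562 on replicate 2), and without replicate 1, with the library of somatic profile kept, it was 0.34 (adjusted p = 0.531). At the first step 6 of 19 meiosis genes rose (12 adjusted over the list alone), with the synaptonemal complex gene Sycp1 at 2.01 ± 0.28 and Dmc1 at 1.84 ± 0.32 (camera adjusted p = 2.87e-19, adjusted p = 0.00316 with an estimated correlation). With all arrays Stra8 alone was called at this step, and 5 genes when adjusted over the list alone (camera adjusted p = 0.165). At the second 12 rose (16 adjusted over the list alone), with Sycp2 at 2.50 ± 0.27 and Prdm9 at 2.49 ± 0.27. Outside the list Spata22 rose by 3.42 ± 0.23, the telomere attachment gene Terb1 by 3.11 ± 0.26 and Tex12 by 3.03 ± 0.46. The list had an adjusted p = 6.21e-31 (adjusted p = 1.53e-04 with an estimated correlation), and 17 of its genes rose with all arrays. Pluripotency genes fell at the second step, 12 of 20 called and none higher (17 adjusted over the list alone), with Dppa2 at -2.14 ± 0.24, Nanog at -2.09 ± 0.27 and Zfp42 at -1.99 ± 0.25 (adjusted p = 1.86e-13, adjusted p = 0.0320 with an estimated correlation). With all arrays 1 fell at this step (adjusted p = 0.591) and 5 at the first (adjusted p = 1.14e-22, adjusted p = 0.129 with an estimated correlation). Tdgf1 fell over both steps (-2.44 ± 0.29 and -1.59 ± 0.29). At the first step Mael (1.25 ± 0.25), Tdrd1 (1.01 ± 0.25), Tdrd9 and Tdrd7 of the male germ fate and piRNA list rose and Morc1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00508, adjusted p = 0.461 with an estimated correlation). With all arrays this list went the other way, with Morc1 alone called, at -1.55 ± 0.31 (adjusted p = 0.00271, adjusted p = 0.482 with an estimated correlation). At the second the phosphofructokinase gene Pfkp fell (-2.42), as did the nucleosome-binding gene Hmgn5 (-2.39) and the embryonic globin gene Hbb-y (-2.65), which blood cells express.

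For the first step limma called 213 genes, 172 higher and 41 lower, against 352 (266 and 86) with all arrays, and 107 were shared. The somatic genes Wt1os, Itga8 and B2m were among the largest rises with all arrays. Leaving out a TS13 array gave 133 (replicate 2) and 135 (replicate 3) genes, and leaving out a TS24 array gave 1199 (replicate 1) and 855 (replicate 2). Without TS24 replicate 1 or 2 the library of somatic profile stayed beside the other array of that group. Those counts do not measure the stability of a germ cell step. For the second step it called 1561, 327 higher and 1234 lower, against 2185 (502 and 1683) with all arrays, of which 1030 were shared. The median of all genes moved by -0.153 at this step (-0.188 with all arrays), and the split turned under scaling, to 1602 higher and 1096 lower after quantile normalization and 1482 and 1213 after centring with all arrays. Single falls near that median therefore rest on the scaling. For the first step the splits were 229 and 187, and 220 and 220. Without TS34 replicate 1, 2 or 3 the all-array count of the second step was 3804, 957 or 618.

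In XY germ cells the early step was small, and at the later one genes of the male germ fate and piRNA list rose. From TS13 to TS24 Mgst2 rose by 2.89 ± 0.37, Hesx1 by 2.16 ± 0.24, the helicase gene Ddx43 by 2.13 ± 0.40 and Cst9 by 2.01 ± 0.45, while AU015836 (-2.78 ± 0.65), Phlda2 (-2.45 ± 0.42) and the metallothionein gene Mt2 (-2.02) fell. Cst9 is on the Sertoli list, of which Hsd17b3 also rose (0.96 ± 0.21) and Sox9 was not called (0.14 ± 0.23). Of the meiosis list Sycp2 (1.89 ± 0.38) and Sycp1 (1.59 ± 0.39) rose (3 adjusted over the list alone), and Stra8 was not called in either step (camera adjusted p = 0.00701, adjusted p = 0.723 with an estimated correlation). At the second step Sycp2 rose again, by 1.65 ± 0.38, and Sycp1 was not called (1.45 ± 0.39, adjusted p = 0.0520). The arrays of the stages did not overlap for Sycp1. Its SE rests on a spread that includes the library of somatic profile, with an SD in XX germ cells at TS24 of 1.51 with that library and 0.35 without it. A halt in the rise of Sycp1 is therefore not shown. From TS24 to TS34 Nanos2 rose by 3.43 ± 0.23 (adjusted p = 2.13e-12), the RNA export gene Nxf2 by 2.65 ± 0.27 and the piRNA factor gene Gtsf1 by 2.50 ± 0.28, and the TFIID subunit gene Taf7l also rose. The largest falls were those of the surrogate light chain gene Vpreb1 (-2.10 ± 0.48), the vesicle SNARE gene Vamp8 (-2.00 ± 0.34), Eid3 (-1.98 ± 0.43), Efcab10 (-1.90), Gmfg (-1.87) and Abracl (-1.85). Of 19 male germ fate and piRNA genes 6 rose and none fell (7 adjusted over the list alone), with Tdrd1 at 1.65 ± 0.27, Piwil4 at 1.64 ± 0.22 and Morc1 at 1.48 ± 0.31 (camera adjusted p = 1.71e-17, adjusted p = 0.0728 with an estimated correlation). The cell cycle list moved down, with a median of -0.42, although Mcm4 alone was called, at -1.03 ± 0.24 (camera adjusted p = 2.36e-05, adjusted p = 0.786 with an estimated correlation). The first step had 106 genes (60 higher, 46 lower) and the second 202 (88 and 114), and with the spread estimated without the library of somatic profile 263 and 480. Without TS13 replicate 1 or 3 or TS24 replicate 1 or 2 the first count was 48, 64, 70 or 39. Without TS24 replicate 1, 2 or 3 or TS34 replicate 1 or 3 the second was 121, 117, 87, 82 or 114, and quantile normalization turned its split to 171 higher and 108 lower (centring, 146 and 125).

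**Figure D3:**
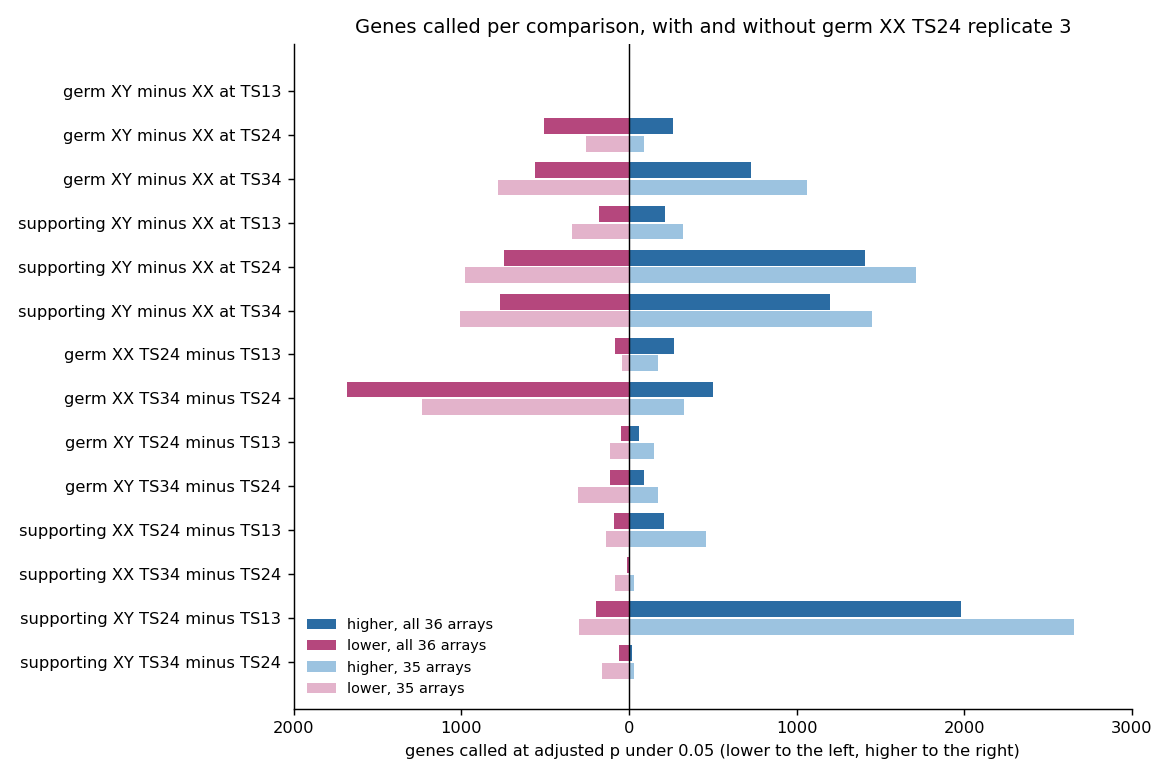
Genes called at adjusted p under 0.05 in the 14 comparisons of 2 groups, with bars to the right for higher and to the left for lower and pale bars for the fit of 35 arrays. Counts ran from 5 (germ XY minus XX at TS13) to 2185 (germ XX TS34 minus TS24) with all arrays.

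In supporting cells the sexes already differed at TS13, where both came from the Sry line. Sry was higher in XY by 3.67 ± 0.21 (means 11.84 and 8.17) and its target Sox9 by 3.23 ± 0.23. Fgf9, a growth factor of testis determination, was higher by 3.66 ± 0.18, the coactivator gene Ppargc1a by 3.90 ± 0.25 and the ETS factor gene Etv5 by 3.65 ± 0.35. The activin antagonist gene Fst was lower at -3.50 ± 0.48, the cystine transporter gene Slc7a11 at -2.96 ± 0.21, Bmp2 at -2.76 ± 0.47 and the growth factor gene Ereg at -2.33 ± 0.41, with Xist at -4.96 ± 0.51. Of 25 Sertoli genes 10 were higher and none lower (12 adjusted over the list alone), with Cst9 at 2.70 ± 0.45 and Cbln4 at 2.35 ± 0.22 (camera adjusted p = 2.22e-42, adjusted p = 8.47e-06 with an estimated correlation). Amh was not called (means 6.10 and 5.90). Of 15 pregranulosa genes 6 were lower and none higher (7 adjusted over the list alone), among them Irx3 at -1.32 ± 0.28, Wnt4 at -1.18 ± 0.31 and Rspo1 at -1.15 ± 0.31, a ligand and an enhancer of WNT signalling (adjusted p = 3.01e-10, adjusted p = 0.0317 with an estimated correlation). WNT targets went both ways, Lef1 lower (-1.55 ± 0.22), Ccnd1 (1.42 ± 0.28) and Lgr5 (1.37 ± 0.36) higher. Of the interstitial and stromal list Pdgfra was higher by 1.80 ± 0.50 and Ptch1 by 0.92 ± 0.23. Nr2f1 (-0.99 ± 0.28, adjusted p = 0.0509) and Nr2f2 (-1.13 ± 0.46) of that list lay lower, with no overlap between the sexes, and were not called. Their SE rests on a spread that includes the germ library of somatic profile. The cell cycle list lay higher in XY with a median of 0.27, 1 gene called (Cdk1, 0.93 ± 0.26) and 6 adjusted over the list alone (camera adjusted p = 5.07e-09, adjusted p = 0.145 with an estimated correlation). Limma called 397 genes, 215 higher and 182 lower, and the split was 387 and 204 after quantile normalization and 321 and 170 after centring. With the spread estimated without the germ library of somatic profile it called 664 (323 and 341), and without XX replicate 2 or XY replicate 3 it called 254 or 250.

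At TS24 the Sertoli list was higher in XY almost in full. The XY cells came from the Sox9 line and the XX cells from the Sry line here and at TS34, so sex and mouse line cannot be told apart in these comparisons. Hsd17b3, whose enzyme makes testosterone from androstenedione, was higher by 5.89 ± 0.21 (means 11.51 and 5.62), Cst9 by 5.43 ± 0.45, Mybl1 by 4.86 ± 0.35, the Slit receptor gene Robo1 by 4.66 ± 0.24 and the tescalcin gene Tesc by 4.14 ± 0.24, and Amh was higher too. Of 25 Sertoli genes 23 were higher and none lower, also adjusted over the list alone (camera adjusted p = 5.75e-47, adjusted p = 7.34e-06 with an estimated correlation). Fst was lower at -5.48 ± 0.48, the collagen gene Col12a1 at -4.70 ± 0.42, Egfl6 at -4.66 ± 0.49 and the antiviral gene Ifitm3 at -4.58 ± 0.28. Of 15 pregranulosa genes 7 were lower (9 adjusted over the list alone), with Bmp2 at -3.93 ± 0.47 and the cyclin-dependent kinase inhibitor gene Cdkn1b at -2.95 ± 0.57 (adjusted p = 1.24e-09, adjusted p = 0.0303 with an estimated correlation). Of 19 cell cycle genes 15 were higher in XY (16 adjusted over the list alone), among them the checkpoint kinase gene Bub1 (3.13 ± 0.40), Top2a (3.19 ± 0.29) and Mki67 (3.17 ± 0.27). The list had an adjusted p = 5.47e-20 and an adjusted p = 0.0102 with an estimated correlation. Of 21 matrix genes 6 were higher, with Col18a1 at 2.34 ± 0.22 and Col9a3 at 1.74 ± 0.21 (adjusted p = 0.00963, adjusted p = 0.589 with an estimated correlation). The gonadal primordium factors Lhx9 and Emx2 were lower (-4.08 ± 0.52 and -3.15 ± 0.36) and Nr5a1 higher (1.03 ± 0.31). Sry itself had means of 8.57 in XY and 8.02 in XX and was not called. Limma called 2154 genes, 1406 higher and 748 lower.

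At TS34 the Sertoli, pregranulosa and cell cycle lists again parted the sexes, with 1969 genes called, 1201 higher and 768 lower. Hsd17b3 was higher in XY by 6.30 ± 0.21, Cst9 by 5.69 ± 0.45, Amh by 3.93 ± 0.21 and Etd by 3.91 ± 0.28, and 23 of 25 Sertoli genes were higher (camera adjusted p = 5.40e-52, adjusted p = 3.12e-06 with an estimated correlation). Fst was lower at -5.31 ± 0.48, the imprinted gene Zim1 at -4.25 ± 0.56 and the splicing factor gene Mbnl3 at -4.10 ± 0.42. Of 15 pregranulosa genes 8 were lower (9 adjusted over the list alone), with Irx3 at -2.74 ± 0.28 and Runx1 at -2.44 ± 0.39 (adjusted p = 1.78e-10, adjusted p = 0.0218 with an estimated correlation). Cell cycle genes were again higher, 15 of 19, with Cdk1 at 3.38 ± 0.26 (16 adjusted over the list alone, adjusted p = 2.44e-23, and adjusted p = 0.00693 with an estimated correlation). Of 8 steroidogenic genes 4 were higher (5 adjusted over the list alone), the lyase gene Cyp17a1 by 1.94 ± 0.24, the side-chain cleavage enzyme gene Cyp11a1 by 1.65 ± 0.24, Star by 1.36 ± 0.21 and Scarb1 by 0.96 ± 0.25 (adjusted p = 9.86e-05, adjusted p = 0.0243 with an estimated correlation). Of 12 WNT targets 4 were lower, with Axin2 at -1.97 ± 0.20 and Lef1 at -1.66 ± 0.22 (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.0101, adjusted p = 0.269 with an estimated correlation). Of 15 cholesterol synthesis genes 5 were higher, with Nsdhl at 1.97 ± 0.29 (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0436, adjusted p = 0.514 with an estimated correlation). Of 11 dissociation stress genes 4 were lower in XY, with Fosb at -2.06 ± 0.40 (5 adjusted over the list alone, adjusted p = 0.00117, adjusted p = 0.448 with an estimated correlation). Of 21 matrix genes 3 were higher, with Col18a1 at 1.55 ± 0.22 (adjusted p = 0.0436, adjusted p = 0.514 with an estimated correlation). Of the gonadal progenitor list Lhx9 (-3.67 ± 0.52) and Emx2 (-2.58 ± 0.36) were lower (adjusted p = 0.854). The retinaldehyde reductase gene Dhrs3 was lower (-3.56 ± 0.39) and the retinoic acid hydroxylase gene Cyp26b1 higher (1.32 ± 0.22).

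**Figure D4:**
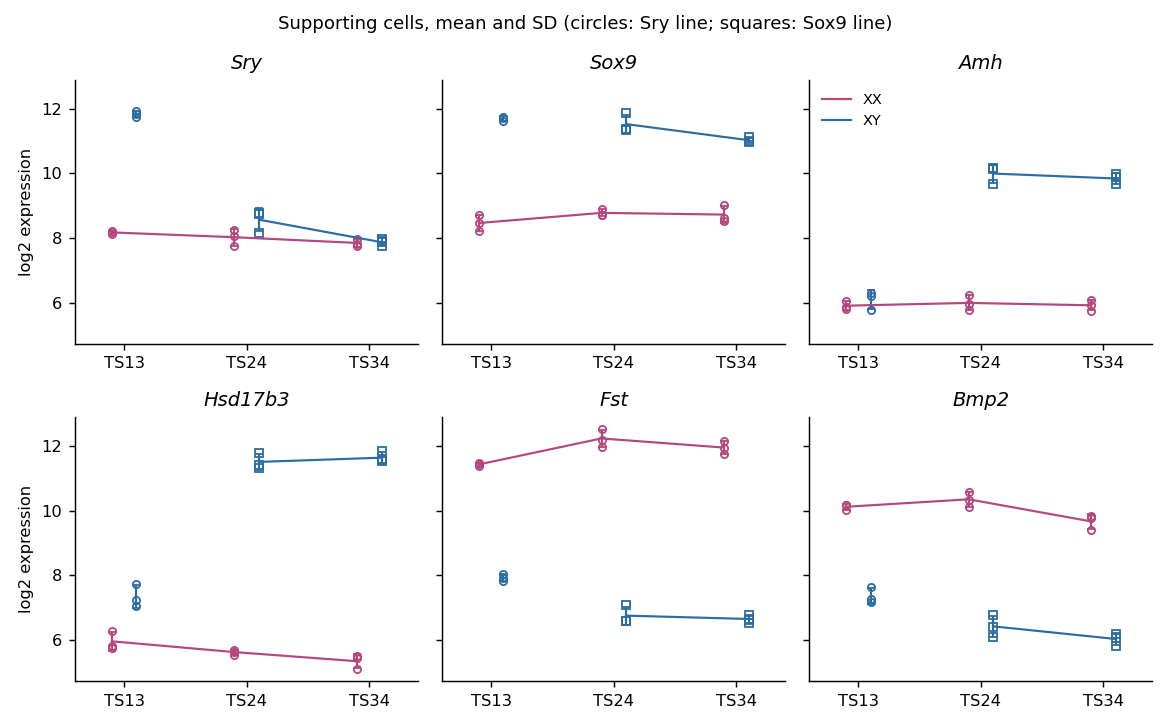
Expression (log2) of 6 genes in supporting cells by stage and sex, with points for arrays, error bars of 1 SD, circles for the Sry line and squares for the Sox9 line, and no line drawn in XY from TS13 to TS24, where the mouse line changed. Hsd17b3 had means of 11.51 and 11.64 in XY against 5.62 and 5.34 in XX at TS24 and TS34, and Sry was high at TS13 in XY alone.

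XX supporting cells, all from the Sry line, changed mainly at the first step. Egfl6, a secreted protein gene of the epidermal growth factor repeat family, rose by 4.05 ± 0.49 from TS13 to TS24, Lrrn1 by 3.08 ± 0.54, the hydroxysteroid dehydrogenase gene Akr1c14 by 2.90 ± 0.23 and Cntn4 by 2.67 ± 0.40. The protocadherin gene Pcdh20 (-2.89 ± 0.29), the pancreatic lipase related gene Pnliprp2 (-2.53), the forkhead gene Foxd1 (-2.49) and Robo1 (-2.44) fell. Of the interstitial and stromal list Nr2f1 fell (-1.16 ± 0.28), while Pdgfra (-1.03 ± 0.50), Nr2f2 (-0.83 ± 0.46) and Pdgfrb (0.17 ± 0.31) were not called. For Pdgfra and Nr2f2 the arrays of these stages did not overlap. Their SE rests on a spread shared with the germ library of somatic profile. That library had Pdgfra at 10.60 and Nr2f2 at 10.47, against 6.86 and 7.29 on the other arrays of its group. Pdgfra and Nr2f2 are therefore not shown to be unchanged. Of 12 retinoic acid genes 3 rose, Aldh1a1 (2.10 ± 0.40), Aldh1a2 (1.74 ± 0.45) and Stra6 (1.04 ± 0.19), which synthesise retinoic acid or import retinol, with 3 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.606). Of WNT targets Lgr5 (1.52 ± 0.36) and Rnf43 (0.79 ± 0.21) rose (6 adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.778 with an estimated correlation), and the cholesterol synthesis gene Idi1 (-2.19) and Cyp11a1 (-1.80) fell. At the second step the matrix calcification inhibitor gene Mgp rose by 1.93 ± 0.35, the thrombospondin gene Thbs2 by 1.36 ± 0.19 and Mro by 1.38 ± 0.23, while Sprr2d (-3.50 ± 0.49), Pnliprp2 (-2.96) and Slc7a11 (-1.74) fell. Mro is on the Sertoli list, of which Gatm rose at the first step (1.96 ± 0.51) and Sox9 was not called at either. The first step had 296 genes (209 higher, 87 lower), and 592 with the spread estimated without the germ library of somatic profile. It was 180, 174, 179 or 195 without TS13 replicate 2 or 3 or TS24 replicate 1 or 2. The second had 20 (6 and 14), 113 with that spread, and 13 without TS24 replicate 2 or TS34 replicate 2. The median of all genes moved by 0.106 and by -0.135 over the 2 steps, and after quantile normalization the splits were 171 higher and 157 lower, and 22 and 15 (centring, 172 and 118, and 16 and 13).

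XY supporting cells changed from the Sry to the Sox9 line between TS13 and TS24, so this step carries a change of mouse line. Amh rose by 3.90 ± 0.21, Hsd17b3 by 4.17 ± 0.21, the cystatin family gene Cstdc1 by 4.06 ± 0.31 and Defb19 by 3.86 ± 0.32, while Sry (-3.28 ± 0.21), Taf7l (-3.69), Dock4 (-3.90) and Ifitm3 (-3.26) fell. Of 25 Sertoli genes 18 rose and none fell (19 and 1 adjusted over the list alone, camera adjusted p = 1.87e-19, adjusted p = 0.00359 with an estimated correlation). Of 19 cell cycle genes 13 rose (15 adjusted over the list alone), with Ccnb2 at 2.50 ± 0.31 (adjusted p = 5.69e-10, adjusted p = 0.200 with an estimated correlation). Of 21 matrix genes 8 rose, with Col9a3 at 1.70 ± 0.21 (adjusted p = 0.00780, adjusted p = 0.380 with an estimated correlation). Of gonadal progenitor genes Lhx9 (-2.74), Emx2 (-2.12), Gadd45g (-1.15) and Sry fell, and Insr rose by 1.23 ± 0.32, Map3k4 by 0.79 ± 0.22 and Cbx2 by 0.71 ± 0.21 (adjusted p = 9.28e-05, adjusted p = 0.254 with an estimated correlation). From TS24 to TS34, within the Sox9 line, Cyp17a1 rose by 1.68 ± 0.24 and Cyp11a1 by 1.18 ± 0.24 (2 of 8 steroidogenic genes, also adjusted over the list alone, adjusted p = 5.81e-07, and adjusted p = 0.0128 with an estimated correlation). Their means at TS34 were 7.47 and 7.06. Star (0.32 ± 0.21), Hsd3b1 (0.38 ± 0.21) and Hsd3b6 (-0.41 ± 0.21) were not called. Which cells of the sorted fraction express these genes was not tested. Cst12 rose by 2.19 ± 0.52 and the catenin gene Ctnna2 by 1.74 ± 0.20, while Ifitm1 (-1.91), the aminopeptidase gene Anpep (-1.88) and Fgf9 (-1.12) fell. The cholesterol synthesis list moved up with a median of 0.30 and no gene called by limma (camera adjusted p = 5.81e-07, adjusted p = 0.121 with an estimated correlation), where 1962 of all genes had an unadjusted p under 0.05. The steps had 2180 genes (1984 higher, 196 lower) and 74 (15 and 59). The median of all genes moved by 0.222 and by -0.173, and after quantile normalization the splits were 856 and 551, and 33 and 35 (centring, 1250 and 382, and 36 and 38). Without TS13 replicate 3 or TS24 replicate 1 the first count was 1289 or 1290. Without TS24 replicate 1 or 3 or TS34 replicate 1, 2 or 3 the second was 22, 48, 22, 33 or 27, and it was 187 with the spread estimated without the germ library of somatic profile.

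The sex differences themselves changed between TS13 and TS34 in both cell types. In germ cells Nanos2 gained 3.82 ± 0.33 in XY relative to XX and Mgst2 4.10 ± 0.52, while Stra8 went down (-4.89 ± 0.49) with Meioc (-4.49 ± 0.53). Of the meiosis list 6 of 19 genes were called, all down (9 adjusted over the list alone). Sycp1 (-1.13 ± 0.55), Sycp2 (-0.53 ± 0.54) and Sycp3 (-0.37 ± 0.82) were not called. Limma called 286 genes, 148 up and 138 down, and 645 with the spread estimated without the library of somatic profile. The count was 187, 159 or 180 without XX TS13 replicate 3, XX TS34 replicate 3 or XY TS34 replicate 3. In supporting cells Hsd17b3 gained 4.92 ± 0.29 and Amh 3.73 ± 0.30, and 15 of 25 Sertoli genes went up while Fgf9 went down at -1.65 ± 0.25 (18 and 3 adjusted over the list alone). Here 527 genes were called, 348 up and 179 down, and 858 with that other spread, and the change of mouse line enters each of these values.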

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

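Of the tests weighed here, those for the swap of arrays, for scaling and the array of somatic profile behind the X-linked difference, for the mouse line, the comparison of germ-specific genes with the cell cycle list, and the sorting of splits by the sexes at TS34 were chosen after the result was seen. A test of the difference of differences singled out the genes whose XY minus XX difference at TS34 differed from that at TS13. Groups of 3 arrays were not tested for single arrays far from the others.

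In germ cells 286 genes differed in this way. The sex difference went up for Mgst2 (4.10), Nanos2 (3.82), Hesx1 (3.37), the fatty acid binding protein gene Fabp9 (3.13), the diacylglycerol kinase gene Dgka (2.92) and Morc1 (2.67). It went down for Stra8 (-4.89), Meioc (-4.49), Meiob (-3.96), M1ap (-3.90), AU015836 (-3.81) and Spata22 (-3.69). By camera the meiosis list went down (adjusted p = 2.13e-18, and adjusted p = 0.0537 with an estimated correlation). The lists of germ identity and pluripotency (adjusted p = 0.00492, adjusted p = 0.873 with an estimated correlation), male germ fate and piRNA (1.30e-04, adjusted p = 0.584 with an estimated correlation) and Nodal signalling (1.42e-04, adjusted p = 0.0537 with an estimated correlation) went up.

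In supporting cells 527 genes differed in this way, and the XY mouse line changed between the stages compared. The sex difference went up for Hsd17b3 (4.92), Amh (3.73), Cstdc1 (3.48), Sel1l3 (3.45), the mitotic kinesin gene Kif15 (3.42) and Jam2 (3.33). It went down for Anpep (-4.40), Cav1 (-3.91), Egfl6 (-3.89), Calcrl (-3.71), Sry (-3.65) and Zim1 (-3.54). By camera the Sertoli list (adjusted p = 6.14e-21, adjusted p = 0.00234 with an estimated correlation), the cell cycle list (7.29e-17, adjusted p = 0.0320 with an estimated correlation) and the steroidogenic list (3.96e-04, adjusted p = 0.0698 with an estimated correlation) went up. The lists of pregranulosa genes (0.00131, adjusted p = 0.303 with an estimated correlation), WNT targets (3.67e-04, adjusted p = 0.0933 with an estimated correlation), retinoic acid genes (0.00667, adjusted p = 0.247 with an estimated correlation) and dissociation stress genes (3.96e-04, adjusted p = 0.303 with an estimated correlation) went down, as did the Y-linked list (0.0334, adjusted p = 0.303 with an estimated correlation), of which Sry was called.

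The library labelled germ XX TS24 replicate 3 has a somatic profile. A swap with a supporting array of this series is excluded, since 0 of 18 arrays labelled supporting correlated better with germ than with supporting arrays. Germ cells mixed with somatic cells are excluded as well, since over 93 germ-specific genes the library held a median of 0.49 percent of the germ level, where supporting arrays held -0.86 to 0.56 percent. A wrong label or an outside sample of interstitial or stromal cells remains possible, since 8 of 13 interstitial and stromal genes lay above all 9 XX supporting arrays, with Pdgfra at 10.60 and Dcn at 10.12 against highest values of 8.16 and 6.82. Chance would give 10 percent of them, but only for an array drawn like those 9. This library was picked for its odd profile, and the share of all genes above those arrays was not counted. Genes of supporting cells lay near their level on XX supporting arrays as well (Kitl 11.18 against a mean of 11.18, Lhx9 11.12 against 10.73), and the endothelial genes Kdr (8.33) and Cdh5 (7.67) lay above the highest of these arrays (6.75 and 7.09), so which somatic cells the library holds is left open, and no biological explanation was tested.

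X-linked genes lie lower in XY than in XX germ cells at TS24 and TS34. A shift common to all genes of an array cancels in this gap by construction, so the gap cannot test it. Differences between the distributions of the arrays are excluded as the whole cause, since the gap at TS24 was -0.200 after quantile normalization. The array of somatic profile is excluded as the whole cause too, since without it the gap at TS24 was also -0.200. A shift that other chromosomes also show is excluded, since 0 of 19 autosomes had as large a gap, the largest being 0.042 at TS24 and 0.050 at TS34. X dosage that differs by sex is left open, since the values that bear on it, every XX array above every XY array at 2 of 2 stages (TS24 and TS34), restate the pattern. At TS13 the sexes did not overlap either, with XX arrays down to -0.044 and XY arrays up to -0.072. With an estimated correlation the gap did not pass the test under the scaling used in the report.

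Cell cycle genes lie higher in XY than in XX supporting cells at TS24 and TS34. The scaling of the arrays is excluded, since the median difference of the list was 1.88 after quantile normalization against 1.89 at TS24 (1.46 against 1.43 at TS34). Germ cell RNA in the XY supporting fraction is excluded, since the germ-specific genes, at least 8-fold higher in germ cells, differed by a median of 0.05 at TS24 and 0.06 at TS34, against 1.89 and 1.43 for the cell cycle list, which germ cells exceed supporting cells in by a median of only 1.62. The bound set beforehand, the median standard error of these genes (0.49), is met as well but is too wide to exclude this alone. For the mouse line the data cannot tell, since XY cells changed line with stage, and within the Sry line at TS13 the difference was 0.27, so a sex difference in the division of these cells could not be told apart from a difference between lines.

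All 36 arrays, the library of somatic profile among them, were kept while the arrays of each comparison were regrouped to see how many genes other groupings call. With 10 splits of 6 arrays there are too few for a share under 0.05. In germ cells XY minus XX called 5, 767 and 1291 genes at TS13, TS24 and TS34, and the highest other split called 0, 127 and 3910, so that 1, 1 and 2 splits reached the real count. The split with 3910 genes set XY replicate 1 with XX replicates 2 and 3, which parts the arrays by overall level (medians of tested genes of 6.83 to 7.05 against 7.24 to 7.26), a structure of the samples beside sex. In supporting cells the counts of 397, 2154 and 1969 stood against 1, 1 and 0. For the steps TS13 to TS24 and TS24 to TS34, the counts stood against the highest other split as 352 against 311 and 2185 against 1111 in germ XX, 106 against 0 and 202 against 0 in germ XY, 296 against 2 and 20 against 0 in supporting XX, and 2180 against 1 and 74 against 0 in supporting XY, each reached by the real split alone (1 of 10). Of 100 splits, 14 reached the 286 genes of the germ difference of differences. Of the 13 others 10 kept the sexes at TS34 whole and so carry that sex difference by construction, which makes the share a poor measure of chance. The highest of the remaining splits called 4050, so chance is not excluded. For the supporting one 14 reached the 527 genes (highest other 1149), and this share does not exclude chance either. All 13 others kept the sexes at TS34 whole and so carry that sex difference by construction, so the share says little about chance, and the highest of the remaining splits called 72. For germ minus supporting cells 1 of 100 reached 8917, the highest other calling 2462, and chance is excluded.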

How the results depend on the processing

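The setting without the array of somatic profile, alone or with quantile normalization, and quantile normalization and the estimated correlation for the X-linked test were chosen after the data were seen. Counts of called genes are given where a setting moved them beyond 1.5 times, for XY minus XX at a stage or for a step between stages, and the cause was not tested unless stated. All 17 counts stayed within 1.5 times with the mean of a gene's probe sets, no filter, a filter at the 50th percentile and trend with robust variances. With the replicate number as a block no count of a comparison changed beyond that either, for example 5, 605 and 1042 genes for germ XY minus XX at the 3 stages. With that block 31 of 699 results on named genes became weaker and 5 stronger, and of 180 counts of list members 15 became weaker and 8 stronger. The replicate numbers shared only a number: among 14 comparisons checked, 0 had every same-numbered pair correlated above 0.1, and 2 of 42 pairs did. Of the results on named genes none reversed under any setting. Of 699 such results 662 stayed the same under quantile normalization, 30 became weaker, 6 stronger and 1 moved. Without the array of somatic profile 588 stayed the same, and of 8322 leaving out 1 array 7621 did. For arrays the signal over background sets the limit: genes near the background have compressed differences, so a gene not called there is not shown to be unchanged.

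With a minimum of 2-fold, which by construction leaves fewer genes, germ XY minus XX had 388 genes at TS24 and 631 at TS34, supporting XY minus XX 1198 and 1132, germ XX 226 and 786 over its 2 steps, supporting XY 896 at its first, and germ minus supporting 2203. With array weights germ XY minus XX had 124 at TS24 and 5195 at TS34, supporting XY minus XX 2020 at TS13 and 5732 at TS34, germ XX 84 at its first step, germ XY 219 and 487, supporting XX 1143 and 287, supporting XY 3880 and 799, and the differences of sex differences 1504 in germ and 3082 in supporting cells. With every probe set on its own, which tests more units, germ XY minus XX at TS13 had 14 and germ minus supporting 14240. With median centring germ XY minus XX at TS24 had 1301 and the germ difference of sex differences 481. With quantile normalization germ XY minus XX at TS24 had 1205, supporting XX 37 at its second step, supporting XY 1407 at its first, and the germ difference of sex differences 506.

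Fits on the arrays of the cell type alone use fewer samples and share less of the spread. They gave for germ XY minus XX 132 at TS24 and 715 at TS34, supporting XY minus XX 760 at TS13, germ XX 68 and 779, germ XY 24 and 66, supporting XX 705 and 109, supporting XY 3874 and 279, and for the differences of sex differences 81 and 1011. Fits on the groups compared alone gave for germ XY minus XX 14 at TS13 and 7 at TS24, supporting XY minus XX 640 at TS13 and 4269 at TS34, germ XX 0 and 4, germ XY 324 and 454, supporting XX 124 and supporting XY 221 at the second step, and 564 and 1716. Without the array of somatic profile germ XY minus XX had 344 at TS24, supporting XY minus XX 664 at TS13, germ XX 213 at its first step, germ XY 263 and 480, supporting XX 592 and 113, supporting XY 187 at its second step, and the differences of sex differences 645 and 858. With quantile normalization in addition germ XY minus XX had 2258 at TS34, supporting XY minus XX 921 at TS13 and 2986 at TS34, germ XY 335 and 545, supporting XX 574 and 115, supporting XY 148 at its second step, and the differences of sex differences 935 and 1068.

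Leaving out 1 array at a time, counts ran from 179 to 1912 for germ XY minus XX at TS24, 705 to 1694 at TS34, 250 to 352 for supporting XY minus XX at TS13, 133 to 1199 and 618 to 3804 for the steps of germ XX, 39 to 100 and 82 to 215 for germ XY, 174 to 343 and 13 to 27 for supporting XX, 1289 to 2145 and 22 to 98 for supporting XY, and 159 to 420 for the germ difference of sex differences. The counts of 1912 and 1199 came from leaving out germ XX TS24 replicate 1 with the array of somatic profile kept. They do not measure the stability of germ cell results. With an estimated correlation the X-linked gaps in germ cells of -0.045, -0.192 and -0.154 no longer passed the test, and of 340 list results 259 stayed the same and 81 became weaker. The list tests with an estimated correlation used the values without a further normalization, and quantile normalization was not tried for them. Without the array of somatic profile 5 list results turned direction, with adjusted p now of 0.885 for cell cycle in germ XY minus XX at TS24 and, for the first step of germ XX, 0.995 for pregranulosa, 0.00508 for male germ fate and piRNA, 0.995 for cell cycle and 0.995 for interstitial and stromal genes.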

Other observations

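The genes and arrays of the last paragraph were chosen after their values were seen, and no explanation is weighed here. Germ cells showed sex differences outside the germ cell lists. The LIM homeobox gene Lhx1, on the list of mesonephric epithelium, was higher in XY than in XX germ cells by 1.76 ± 0.25 at TS34 and by 1.64 ± 0.25 at TS24 without the library of somatic profile, and it rose in XY germ cells from TS13 to TS24 by 1.41 ± 0.25. Of the matrix list Fn1 (1.21 ± 0.25) and the laminin gene Lamb1 (1.14 ± 0.22) were higher and Lama1 (-1.15 ± 0.22) lower in XY germ cells at TS34, with adjusted p = 0.598 for the list by camera. The retinoic acid binding protein gene Crabp1 was lower in XY at -1.94 ± 0.30 and Aldh1a1 higher by 1.78 ± 0.40 (list adjusted p = 0.0372, adjusted p = 0.520 with an estimated correlation).

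Some markers of other cell types were higher in germ than in supporting cells. With all arrays, Pecam1, an adhesion gene of endothelial and germ cells, was higher by 3.11 ± 0.19, the epithelial adhesion gene Epcam by 3.07 ± 0.18, Lhx1 by 1.39 ± 0.10 and Tyrobp of the macrophage list by 0.79 ± 0.11. Called were 3 of 13 endothelial genes (camera adjusted p = 0.577), 3 of 8 mesonephric epithelium genes (0.481), 1 of 10 macrophage genes (0.692) and, by limma, 0 of 5 erythroid genes (0.577), where 9649 of all genes had an unadjusted p under 0.05. Of 13 interstitial and stromal genes 5 were lower in germ cells (0.189). The remaining lists had 16 of 19 meiosis genes higher (17 adjusted over the list alone, adjusted p = 1.99e-09), 17 of 19 male germ fate and piRNA genes higher (5.02e-10) and 11 of 15 pregranulosa genes lower and 1 higher (1.34e-05). With an estimated correlation these 3 lists had an adjusted p = 0.127, and without the library of somatic profile 0.00831, 0.00354 and 0.0192. Without it 17 meiosis genes were higher, and of the endothelial list 2 were lower beside the 3 higher.

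The embryonic globin gene Hbb-y differed between arrays of 1 group, with 10.85, 5.49 and 9.54 on the arrays of XX supporting cells at TS24 and 7.53, 10.39 and 11.21 on those of XY supporting cells at TS13. The leukocyte genes Ptprc and Csf1r had group means of 5.73 to 6.23 and 5.22 to 5.74. Foxl2, a factor of the ovarian somatic lineage, had group means of 5.99 to 6.61 in all 12 groups. Among the other arrays of XX germ cells at TS24, replicate 2 had Wt1 at 8.19 and Xist at 8.29, where replicate 1 had 7.18 and 6.60, and replicate 1 had Eif2s3y at 5.73, where replicate 2 had 4.46. The first replicates of XX supporting cells at TS24 and TS34 had Ddx4 at 6.56 and 6.75, where the other arrays of these groups had 4.84 to 5.67.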
